A study of Mus musculus with 12 samples.

How the data were processed

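The data are RNA-seq read counts per gene symbol for 12 libraries of sorted mouse microglia, 4 each from untransplanted, syngeneic and allogeneic mice. Per the labels' protocols, total RNA was isolated with the Picopure kit, only RNA with an integrity value of at least 8 was used, and libraries followed standard Illumina protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to the mouse build mm9. The authors deposited 1 table of raw counts for 24328 gene symbols, and its values are whole numbers. The counting tool, the gene annotation, the strand setting and the handling of reads shared between near-identical genes are not given in the sources used here. Values of overlapping or antisense genes, of pseudogenes such as H2-Ea-ps and Tmem181b-ps, and of families such as the MHC class I and ribosomal protein genes are therefore uncertain. The donor strain, any sequencing batch and the meaning of the replicate numbers are also not given in the sources used here. The reference at hand is another build, so gene names, lengths, GC content and biotypes were used and no coordinates are printed; 23298 symbols matched directly, 669 through a synonym and 361 did not match.

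From the deposited counts, CPM and log2 fold changes were computed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10), which kept 12695 of 18018 genes with any count. Spearman correlations of log2 CPM between libraries of a group were 0.975 to 0.984. The 3 comparisons came from 1 quasi-likelihood fit of all 12 libraries with group means (robust), with Benjamini-Hochberg adjustment and a call at adjusted p under 0.05. The squared biological coefficient of variation was 0.147. Of 39 gene lists fixed before the data were examined, the 38 with at least 5 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01; 11 list genes were not in the table. The genes named follow a rule set at that time. It takes, per comparison, the 6 largest and 6 smallest log2 fold changes among called genes without overlap and with a mean log2 CPM of at least 2, up to 3 members of each list with the smallest p, and every tested member of the study panel. Predicted genes and mitochondrial and small RNA genes were passed over in the first part. Of the genes it gives, 4 are left out of the text for a reason unrelated to their values, and none was put in their place; counts of lists include them. Genes named outside this rule were chosen after their values were seen: Cd38, Cd3e, Ciita, Clec12a, Clk1, Clk4, Ddx3y, Eif2s3y, Folr1, Ifng, Kcnj13, Kdm5d, Kl, Ms4a7, Neat1, Ttr and Uty.

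The method was tested on simulated counts with the real means and library sizes. It called 59.6% of genes changed by 1 log2 unit and 85.0% changed by 2 in allogeneic against syngeneic (12002 genes), 56.1% and 81.8% in syngeneic against control (12040), and 63.0% and 86.7% in allogeneic against control (12046), with 5.26%, 3.55% and 1.33% of calls false. Alternatives were RLE factors, library totals only, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, only the compared groups, a fold change limit, each library left out, the replicate number as a block, camera with an estimated correlation and fry. An offset for GC content and transcript length (loess span 0.3; 12615 tested genes have both) was added after seeing the data.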

Results

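RNA was measured in 12 libraries of microglia, the resident macrophages of the brain, sorted by FACS from wild-type BALB/c mice. The 3 groups held 4 mice each. Control mice were untransplanted. Syngeneic and allogeneic recipients were lethally irradiated, received 5000000 bone marrow cells with 300000 T cells, and were killed on day 14, the peak of graft-versus-host disease (GvHD, the attack of donor T cells on host tissue) per the labels. Library totals were 32652208 to 45439607 counts in control, 36422729 to 46126118 counts in syngeneic, and 35559202 to 42641198 counts in allogeneic libraries (n = 4 each). A group total of 0 counts allows up to 0.0179 CPM (counts scaled to library size) in control and syngeneic and 0.0217 in allogeneic libraries, for counting error only. Throughout, levels are mean CPM ± SD with n = 4, and parentheses after gene names hold the log2 fold change ± SE, and medians of gene lists are of log2 fold changes. Rose and fell refer to genes called by edgeR's quasi-likelihood test at an adjusted p under 0.05. Where a second camera adjusted p directly follows the first, it used an estimated correlation.

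**Figure D1:**
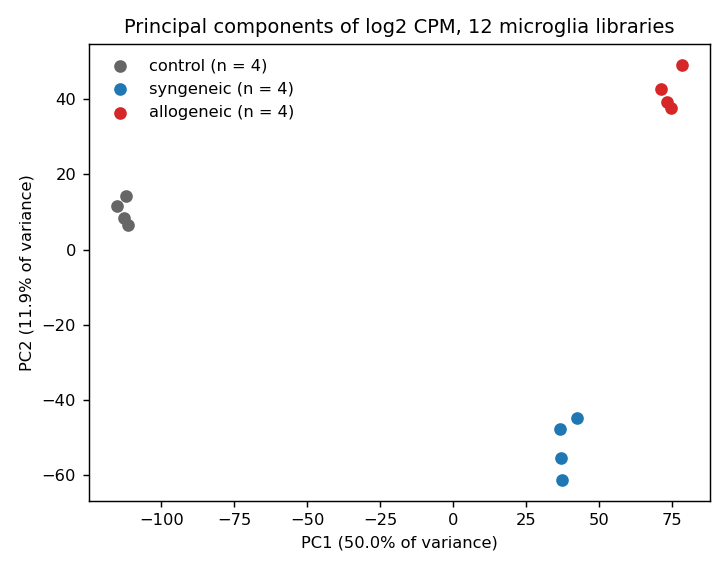
Principal components of log2 CPM for the 12 libraries, 1 point each, coloured by group (n = 4). The first component holds 49.99% of the variance and the second 11.9%, and libraries of a group lie together.

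Allogeneic recipients were compared with syngeneic recipients to ask how GvHD changes microglia beyond irradiation and transplantation themselves. Allogeneic microglia held far more transcripts of antigen presentation. Cd74, the invariant chain that escorts MHC class II molecules, stood at 13689 ± 1467 against 201 ± 34.8 CPM (log2 fold change 6.09, SE 0.14, edgeR adjusted p = 1.8e-14), and the class II chain gene H2-Aa at 1513 ± 189.6 against 16.1 ± 5.50 CPM. Interferon-inducible chemokine Cxcl9, which draws activated T cells, rose to 368 ± 49.3 against 4.63 ± 2.28 CPM, and the cytokine gene Tnf to 14.8 ± 1.96 against 5.44 ± 1.99 CPM (log2 fold change 1.44, SE 0.31, edgeR adjusted p = 0.00298). The homeostatic microglia gene P2ry12, a purine receptor that guides process movement, fell from 17287 ± 868 to 9081 ± 393 CPM. Of 12695 genes tested, 2098 were called, 1288 higher and 810 lower. With library totals only, 2952 were called, 844 higher and 2108 lower, and the median log2 fold change of all genes was -0.22. Among all tested genes, 2631 (20.7%) had the 4 libraries of one group all above or all below the 4 of the other, where exchangeable libraries give 2.86%. The genes with the largest rises among those without overlap were H2-Eb1 (7.76 ± 0.25), H2-Ea-ps (6.80 ± 0.48), H2-Aa (6.55 ± 0.35), Cxcl9 (6.31 ± 0.28), Cd74 (6.09 ± 0.14) and C3 (5.34 ± 0.54), where C3 is the central complement component. The largest falls were those of Fcrls (-2.32 ± 0.12), Adamts16 (-2.22 ± 0.42), Tlr5 (-2.18 ± 0.47), Klhdc8b (-2.14 ± 0.15), Il1rl1 (-2.10 ± 0.39) and Akap5 (-2.08 ± 0.43), where Tlr5 detects flagellin and Il1rl1 is the receptor for interleukin 33. Adamts16 (-3.00 without allogeneic 1) moved over 1.5 times in fold on leaving out that library.

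**Figure D2:**
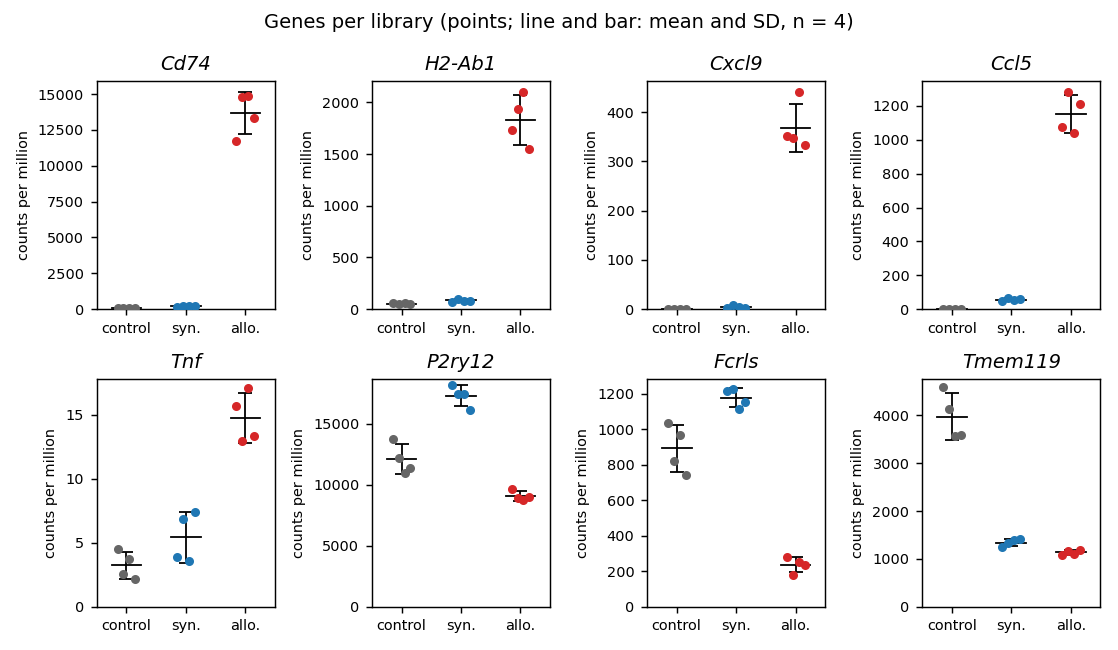
CPM of 8 genes in each library (points), by group, with mean and SD (n = 4); each vertical axis starts at 0. Cd74 reaches 13689 CPM on average in allogeneic libraries against 201 in syngeneic and 60.4 in control libraries, and P2ry12 is lowest in allogeneic libraries.

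Antigen presentation and interferon genes rose together. Among 13 MHC class II presentation genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 3.35). Their camera adjusted p was 6.4e-76 with the preset and 7.2e-05 with an estimated correlation. Cd74 (6.09 ± 0.14), H2-Ab1 (4.45 ± 0.12) and H2-Eb1 (7.76 ± 0.25) ranked first by p. The 20 tested MHC class I presentation genes held 18 that rose and 0 that fell (19 and 0 adjusted over the list alone, median 1.52). For this list camera adjusted p was 1.7e-63 with the preset and 7.9e-04 with an estimated correlation. B2m (1.81 ± 0.07), H2-Q4 (3.32 ± 0.14) and H2-T23 (2.64 ± 0.11) came first by p. Of 30 tested interferon-gamma response genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone, median 3.05, camera adjusted p = 4.4e-53). Ifi47 (3.76 ± 0.18), Irf1 (2.29 ± 0.12) and Gbp7 (2.16 ± 0.12) had the smallest p. Among 30 type I interferon response genes, 28 rose and 0 fell (30 and 0 adjusted over the list alone, median 1.99, camera adjusted p = 6.3e-37 and 0.00330). Bst2 (2.04 ± 0.11), Ifitm3 (2.86 ± 0.18) and Irf7 (2.71 ± 0.21) ranked first by p.

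Most lists of inflammatory mediators held more genes that rose than fell. The 19 tested chemokine genes held 14 that rose and 0 that fell (14 and 0 adjusted over the list alone, median 1.85, camera adjusted p = 3.7e-27). Ccl5 (4.36 ± 0.14), Cxcl9 (6.31 ± 0.28) and Cxcl16 (1.84 ± 0.13) came first by p. Of 16 tested proinflammatory cytokine genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.42, camera adjusted p = 6.8e-10). Il1b (2.80 ± 0.14), Il1a (0.87 ± 0.08) and Tnfsf13b (1.78 ± 0.19) had the smallest p. Among 26 NF-kappaB target genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 3.0e-11). Il1b (2.80 ± 0.14), Bcl2a1a (2.36 ± 0.17) and Icam1 (1.08 ± 0.11) ranked first by p. The 20 tested inflammasome and cell death genes held 10 that rose and 0 that fell (10 and 0 adjusted over the list alone, median 0.61, camera adjusted p = 1.5e-07). Il1b (2.80 ± 0.14), Pycard (0.77 ± 0.07) and Zbp1 (3.46 ± 0.36) came first by p. Of 20 tested complement genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.84, camera adjusted p = 6.8e-09). Cfb (3.96 ± 0.25), C1qa (0.89 ± 0.06) and C1qc (0.78 ± 0.07) had the smallest p. Among 17 costimulation and checkpoint genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 1.7e-09). Slamf8 (1.69 ± 0.12), Icam1 (1.08 ± 0.11) and Cd40 (4.51 ± 0.48) ranked first by p. The 29 tested TAK1 and MAPK pathway genes held 2 that rose and 3 that fell (2 and 3 adjusted over the list alone, median 0.01, camera adjusted p = 0.711), while the mean was -0.02 and the test pointed down, and under library totals the median was -0.19. Tlr2 (1.496 ± 0.15), Mapk8 (-0.84 ± 0.26) and Tlr4 (0.37 ± 0.11) came first by p. Of 16 tested TGF-beta signalling genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.08, camera adjusted p = 0.193), and the list was called lower under library totals (0.0418). Pmepa1 (-0.57 ± 0.08), Smad3 (-0.73 ± 0.12) and Ski (-0.45 ± 0.08) had the smallest p. Mapk8 (0.0534 to 0.130 without syngeneic 2, 4 or allogeneic 1, 2, 3) and Tlr4 (0.0957 to 0.138 without syngeneic 2, 3 or allogeneic 3) lost the edgeR call at these adjusted p. Cd40 (5.42 without syngeneic 2) moved over 1.5 times in fold on leaving out that library.

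Genes of resting microglia fell and genes of activated phagocytes rose. Among 24 homeostatic microglia genes, 0 rose and 18 fell (0 and 19 adjusted over the list alone, median -0.38, camera adjusted p = 1.1e-18). Fcrls (-2.32 ± 0.12), Ecscr (-1.44 ± 0.10) and Gpr34 (-0.94 ± 0.06) ranked first by p. The 24 tested disease-associated microglia genes held 18 that rose and 2 that fell (18 and 3 adjusted over the list alone, median 0.98, camera adjusted p = 9.9e-26). Fth1 (1.34 ± 0.06), Lyz2 (1.52 ± 0.08) and Clec7a (2.57 ± 0.14) came first by p. Of 21 tested phagocytosis receptor genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone, median 0.48, camera adjusted p = 1.3e-07). Clec7a (2.57 ± 0.14), Fcgr4 (3.07 ± 0.21) and Cd300lf (2.62 ± 0.22) had the smallest p. Among 29 lysosomal genes, 18 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.37, camera adjusted p = 1.4e-11). Ctss (0.91 ± 0.05), Ctsc (1.51 ± 0.09) and Ctsz (0.98 ± 0.07) ranked first by p. The 17 tested border-associated macrophage markers held 3 that rose and 2 that fell (3 and 3 adjusted over the list alone, median -0.11, camera adjusted p = 0.895), while the mean was 0.65 and the test pointed up. Siglec1 (3.70 ± 0.28), Stab1 (-0.78 ± 0.09) and Maf (-0.56 ± 0.08) came first by p. Of 25 tested markers of engrafted bone marrow-derived macrophages, 16 rose and 1 fell (20 and 2 adjusted over the list alone, median 1.55, camera adjusted p = 5.9e-22). Cybb (2.99 ± 0.14), Lyz2 (1.52 ± 0.08) and Ms4a6c (2.46 ± 0.15) had the smallest p. Among 19 monocyte markers, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.78, camera adjusted p = 0.00124). Ms4a4c (2.92 ± 0.20), Plac8 (2.71 ± 0.29) and Fn1 (4.199 ± 0.50) ranked first by p.

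Ribosomal and respiratory chain genes rose, but fold changes fell with transcript length (Spearman rho -0.19). Against control, fold changes fell with GC content (-0.29 syngeneic, -0.28 allogeneic) and length (-0.05, -0.11). No fixed list was rerun with the offset, so such effects stay open in every comparison. The 45 tested cytosolic ribosomal protein genes held 44 that rose and 0 that fell (44 and 0 adjusted over the list alone, median 0.88). Camera adjusted p was 1.9e-92 with the preset and 0.00178 with an estimated correlation. Rpl32 (1.22 ± 0.06), Rps20 (1.26 ± 0.07) and Rps24 (1.15 ± 0.07) came first by p. Of 35 tested oxidative phosphorylation genes, 19 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 9.7e-09). Cox4i1 (0.65 ± 0.07), Uqcrh (0.77 ± 0.08) and Ndufa1 (0.72 ± 0.09) had the smallest p. Among 21 glycolysis genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 0.0251 but 0.394), and the call was lost without syngeneic 3 (0.0686). Gapdh (0.70 ± 0.10), Aldoa (0.56 ± 0.09) and Ldha (0.76 ± 0.13) ranked first by p. The 22 tested cholesterol synthesis genes held 2 that rose and 0 that fell (2 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.110), and the list was called higher with the replicate block (0.0173) or without allogeneic 1 (0.0351). Insig1 (0.69 ± 0.18) and Tm7sf2 (0.85 ± 0.30, not called) were among the 3 with the smallest p. Of 30 tested cell cycle genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, median -0.30, camera adjusted p = 0.0200 but 0.285), and the call was lost without syngeneic 4 (0.0774). Mcm4 (-1.27 ± 0.19), Mcm7 (-0.60 ± 0.14) and Mcm5 (-0.71 ± 0.18) had the smallest p. Among 27 p53 target genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.468). Sesn1 (-0.49 ± 0.09), Bax (0.40 ± 0.09) and Fas (1.91 ± 0.49) ranked first by p. The 14 tested senescence genes held 2 that rose and 0 that fell (2 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.623), and under library totals the median was -0.02. Glb1 (0.59 ± 0.12) and Il6 (0.82 ± 0.26) were among the 3 with the smallest p. Of 24 tested immediate early and dissociation genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, median -0.02, camera adjusted p = 0.711), while the mean was 0.06 and the test pointed down. Rhob (-0.57 ± 0.10), Klf6 (0.29 ± 0.08) and Btg2 (-0.31 ± 0.11, not called) had the smallest p. Insig1 (0.0547 without syngeneic 4), Il6 (0.0533 to 0.110 without syngeneic 1, 3, 4 or allogeneic 1, 2, 3) and Klf6 (0.0571 to 0.0648 without syngeneic 3, 4) lost the edgeR call at these adjusted p. Tm7sf2 (0.0437 without syngeneic 2) and Btg2 (0.0112 without allogeneic 2) gained a call at that edgeR adjusted p.

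Markers of cells other than microglia were read beside these changes. Choroid plexus transcripts, a list made after the values were seen, summed to 1806 ± 517 CPM in syngeneic and 608 ± 159.9 in allogeneic libraries, and 3 of 14 fell. Among 9 T cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.895), and under library totals the median was -0.14. The 5 tested NK and cytotoxic cell markers held 3 that rose and 0 that fell (3 and 1 adjusted over the list alone, median 4.36, camera adjusted p = 2.3e-06). Ccl5 (4.36 ± 0.14), Klrb1c (count ratio 107, 95% counting interval 29.1 to 887) and Klrk1 (4.57 ± 1.28) came first by p. Of 6 tested B and plasma cell markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone, median -0.41, camera adjusted p = 0.332). Cd22 (2.49 ± 0.31), Bank1 (-1.23 ± 0.16) and Tnfrsf17 (-1.12 ± 0.23) had the smallest p. Among 11 dendritic cell markers, 2 rose and 3 fell (2 and 3 adjusted over the list alone, median -0.06, camera adjusted p = 0.297), while the mean was 0.16 and the test pointed down. Cst3 (-0.70 ± 0.05), Fscn1 (-1.09 ± 0.09) and Naaa (1.38 ± 0.16) ranked first by p. The 8 tested neutrophil markers held 0 that rose and 0 that fell (0 and 0 adjusted over the list alone, median 1.43, camera adjusted p = 0.475). Of 19 tested astrocyte markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.50, camera adjusted p = 0.399). Glul (-0.34 ± 0.08), Slc1a3 (0.38 ± 0.10) and Aldh1l1 (3.34 ± 1.02) had the smallest p. Among 9 oligodendrocyte lineage markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone, median -0.07, camera adjusted p = 0.623), while the mean was 0.02 and the test pointed down. Enpp2 (-1.64 ± 0.45), Cspg4 (2.06 ± 1.68, not called) and Bcas1 (1.32 ± 1.44, not called) ranked first by p. The 16 tested neuronal markers held 0 that rose and 0 that fell (0 and 0 adjusted over the list alone, median -0.06, camera adjusted p = 0.711). Of 16 tested endothelial and mural markers, 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 0.339). Ly6a (4.91 ± 0.37), Flt1 (5.69 ± 1.53) and Pdgfrb (1.21 ± 0.36) had the smallest p. Among 6 erythroid markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.04, camera adjusted p = 0.711), while the mean was 0.01 and the test pointed down, and under library totals the median was -0.16. The 2 tested sex-linked genes held 1 that rose and 0 that fell (1 and 1 adjusted over the list alone, median -1.69 or -0.27 with genes of 3 or fewer counts at their bound). Xist (1.66 ± 0.31) and Tsix (at least 4.62-fold lower, not called) came first by p. Klrk1 (0.0551 to 0.0826 without syngeneic 1, 2, 4 or allogeneic 1, 2, 3, 4), Slc1a3 (0.0515 without syngeneic 2), Aldh1l1 (0.0641 to 0.0718 without syngeneic 1, 3 or allogeneic 2, 3), Enpp2 (0.0658 to 0.0802 without syngeneic 1 or allogeneic 1, 3, 4) and Pdgfrb (0.0684 to 0.0993 without syngeneic 1, 2, 4 or allogeneic 1, 3) lost the edgeR call at these adjusted p. Klrb1c (log2 6.42 to 8.62 without syngeneic 1), Aldh1l1 (4.57 without syngeneic 2), Cspg4 (2.74 without syngeneic 1 or -0.41 without allogeneic 4), Bcas1 (0.49 without allogeneic 3), Flt1 (9.44 without syngeneic 3) and Tsix (log2 -5.05 to 0 without syngeneic 1) moved over 1.5 times in fold on leaving out that library.

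A panel of 25 genes was drawn up from knowledge of the study, so its direction is not independent evidence. In it 13 rose and 7 fell in allogeneic against syngeneic libraries (14 and 7 adjusted over the list alone, camera adjusted p = 2.0e-27). The counts were 14 and 7 in syngeneic against control (16 and 7 adjusted over the list alone, camera adjusted p = 0.0876, and the list was called higher without syngeneic 1 (0.0201)) and 16 and 8 in allogeneic against control (16 and 8 adjusted over the list alone, camera adjusted p = 4.6e-08). Values stand for allogeneic against syngeneic, syngeneic against control and allogeneic against control. Members named here that rose in the first were Tnf (1.44 ± 0.31, 0.75 ± 0.31 not called, 2.19 ± 0.32), Il1b (2.80 ± 0.14, 1.45 ± 0.14, 4.25 ± 0.15), Il6 (0.82 ± 0.26, 1.11 ± 0.26, 1.93 ± 0.26), Cd74 (6.09 ± 0.14, 1.73 ± 0.11, 7.82 ± 0.15), H2-Aa (6.55 ± 0.35, 1.62 ± 0.31, 8.17 ± 0.38), H2-Ab1 (4.45 ± 0.12, 0.68 ± 0.11, 5.13 ± 0.12), H2-Eb1 (7.76 ± 0.25, -0.09 ± 0.23 not called, 7.66 ± 0.25), Cd86 (0.40 ± 0.07, 0.27 ± 0.07, 0.66 ± 0.07), Cxcl10 (2.58 ± 0.28, 4.57 ± 0.33, 7.15 ± 0.36), Ccl5 (4.36 ± 0.14, 4.91 ± 0.16, 9.27 ± 0.19), Aif1 (0.78 ± 0.06, 1.01 ± 0.06, 1.79 ± 0.07) and Ptprc (0.28 ± 0.07, 0.17 ± 0.07 not called, 0.45 ± 0.07). Members that fell were Nfkb1 (-0.56 ± 0.09, -0.31 ± 0.09, -0.87 ± 0.10), Rela (-0.35 ± 0.11, -1.12 ± 0.11, -1.48 ± 0.11), Mapk14 (-0.31 ± 0.10, -0.45 ± 0.10, -0.77 ± 0.10), P2ry12 (-0.93 ± 0.06, 0.52 ± 0.06, -0.41 ± 0.06), Tmem119 (-0.24 ± 0.07, -1.57 ± 0.08, -1.80 ± 0.08), Cx3cr1 (-0.33 ± 0.08, -0.62 ± 0.08, -0.96 ± 0.08) and Csf1r (-0.29 ± 0.07, -1.70 ± 0.08, -2.00 ± 0.08). Not called were Il33 (1.40 ± 1.54 not called, at least 37.7-fold higher, at least 99.5-fold higher), Cd80 (0.49 ± 0.28 not called, -0.51 ± 0.28 not called, -0.02 ± 0.28 not called), Map3k7 (0.32 ± 0.14 not called, 0.54 ± 0.14, 0.86 ± 0.14), Itgam (-0.12 ± 0.07 not called, 0.32 ± 0.07, 0.20 ± 0.07) and Cnr2 (0.29 ± 0.20 not called, -1.32 ± 0.21, -1.03 ± 0.21). Map3k7 encodes the kinase TAK1 and Cnr2 the cannabinoid receptor 2. Il6 (0.0533 to 0.110 without syngeneic 1, 3, 4 or allogeneic 1, 2, 3), Rela (0.0614 to 0.117 without syngeneic 1, 3, 4 or allogeneic 1, 2, 4), Mapk14 (0.0800 to 0.122 without syngeneic 1, 3, 4 or allogeneic 1, 3, 4) and Tmem119 (0.0510 to 0.0944 without syngeneic 2, 3, 4 or allogeneic 1, 2, 3) lost the edgeR call in allogeneic against syngeneic at these adjusted p. Itgam (0.0469 without syngeneic 1) gained a call in allogeneic against syngeneic at that edgeR adjusted p. Il33 (2.10 without syngeneic 3 or 0.22 without allogeneic 4) moved over 1.5 times in fold in allogeneic against syngeneic on leaving out that library. Tnf (0.0257 to 0.0344 without control 1 or syngeneic 1, 3) and Ptprc (0.00838 without control 4) gained a call in syngeneic against control at that edgeR adjusted p. Il33 (log2 7.73 to 7.05 without syngeneic 3) moved over 1.5 times in fold in syngeneic against control on leaving out that library. Cd86 turned to -0.11, Ptprc to -0.20, Mapk14 to 0.05 and P2ry12 to -0.04 with the GC and length offset in syngeneic against control. Itgam (0.0748 without control 2) lost the edgeR call in allogeneic against control at these adjusted p. Il33 (log2 9.14 to 7.97 without allogeneic 4) moved over 1.5 times in fold in allogeneic against control on leaving out that library. Itgam turned to -0.17 under library totals in allogeneic against control.

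**Figure D3:**
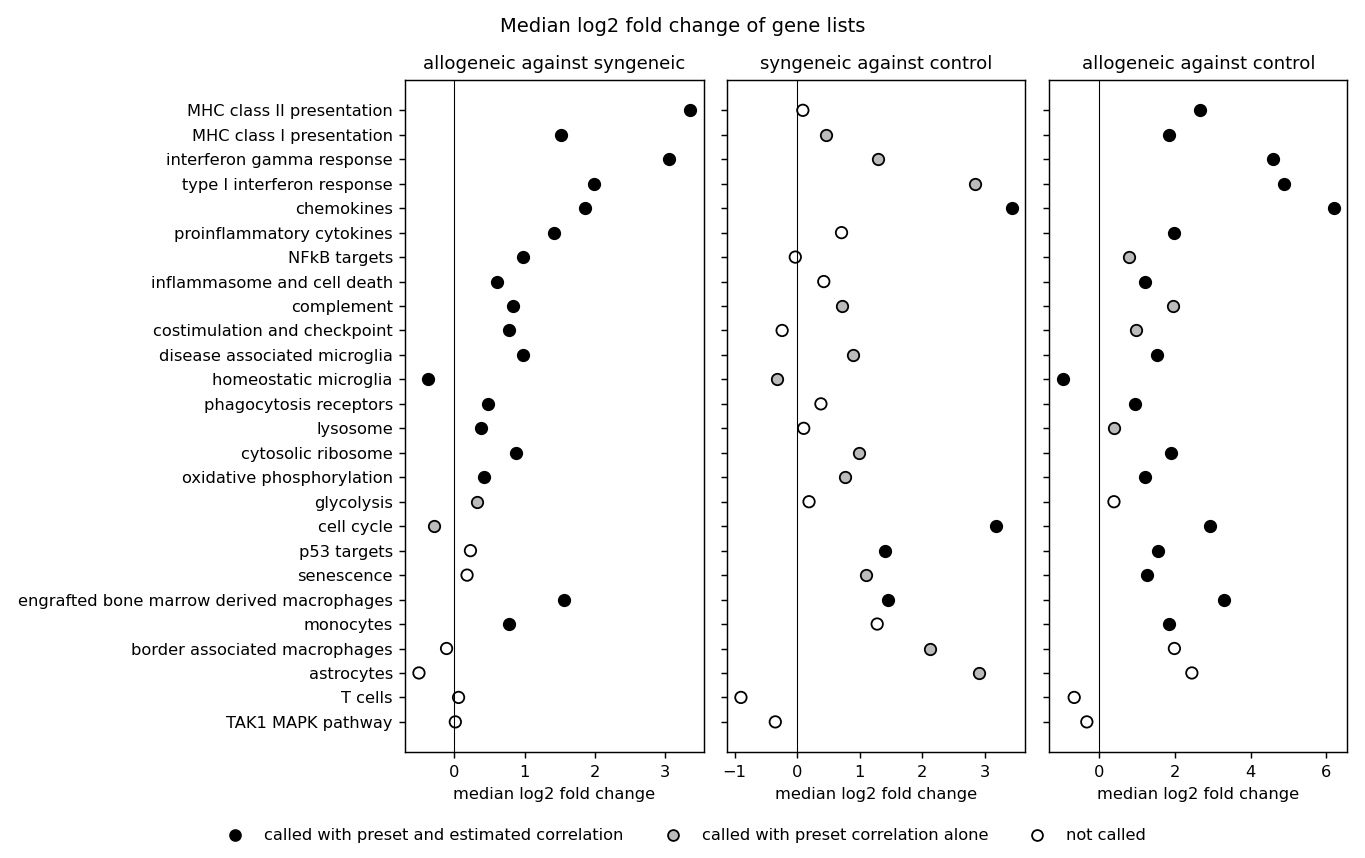
Median log2 fold change of 26 fixed gene lists in each of the 3 comparisons. Filled points were called with preset and estimated correlation, grey points with the preset correlation alone, open points were not called; MHC class II genes have a median of 3.35 in allogeneic against syngeneic libraries and 0.09 in syngeneic against control.

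Syngeneic recipients were compared with untransplanted controls, where effects of irradiation, the graft and an unrecorded batch cannot be told apart. Proliferation genes were higher: Top2a, a topoisomerase of dividing cells, stood at 167 ± 12.99 against 8.16 ± 1.505 CPM (log2 fold change 4.36, SE 0.17, edgeR adjusted p = 1.4e-12), and the cell cycle inhibitor Cdkn1a, a p53 target, at 287 ± 17.5 against 33.3 ± 4.42 CPM (log2 fold change 3.11, SE 0.09, edgeR adjusted p = 1.3e-13). The nuclear RNA Malat1 fell from 5809 ± 882 to 69.0 ± 36.1 CPM. Csf1r, the growth factor receptor that microglia need to survive, fell from 11490.5 ± 1079 to 3525 ± 337 CPM. Of 12695 genes tested, 6610 were called, 3357 higher and 3253 lower. With library totals only, 6691 were called, 2723 higher and 3968 lower, and the median log2 fold change of all genes was -0.20. Among all tested genes, 6353 (50.04%) had no overlap between the groups, where exchangeable libraries give 2.86%. The largest rises without overlap were those of Iigp1 (count ratio 1166, 95% counting interval 209 to 46109.6), Cxcl9 (count ratio 789.6, 95% counting interval 141 to 31228), Cxcl13 (7.58 ± 0.35), Cxcl11 (5.88 ± 0.57), AI607873 (5.53 ± 0.27) and Ass1 (4.95 ± 0.64), where Cxcl13 attracts B cells. The largest falls were those of Malat1 (-6.40 ± 0.51), Snhg20 (-5.81 ± 0.25), Sfi1 (-4.84 ± 0.14), Tmem181b-ps (-4.74 ± 0.34), Hdac10 (-4.53 ± 0.34) and Xist (-4.42 ± 0.34), where Xist silences an X chromosome. Iigp1 (log2 9.61 to 11.15 without control 2), Cxcl9 (log2 8.99 to 10.52 without control 1), Cxcl11 (7.62 without control 2) and Ass1 (5.71 without control 2) moved over 1.5 times in fold on leaving out that library.

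**Figure D4:**
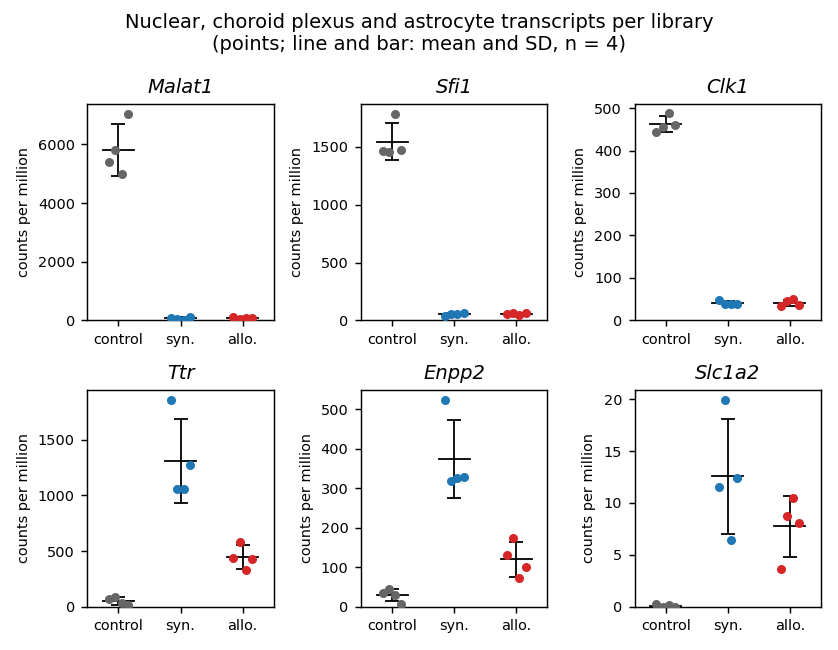
CPM of 6 transcripts in each library (points), by group, with mean and SD (n = 4); each vertical axis starts at 0. Malat1 averages 5809 CPM in control, 69.0 in syngeneic and 82.5 in allogeneic libraries, while the choroid plexus transcript Ttr is highest in syngeneic libraries.

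The interferon response lists and MHC class I genes were called higher with the preset correlation alone. Of 13 tested MHC class II presentation genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.100), and under library totals the median was -0.08, and the list was called higher without syngeneic 1 (0.0459). Ctss (0.87 ± 0.05), Cd74 (1.73 ± 0.11) and H2-DMa (1.05 ± 0.09) had the smallest p. Among 20 MHC class I presentation genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone, median 0.46, camera adjusted p = 0.0248 but 0.522). B2m (1.51 ± 0.07), H2-K1 (1.36 ± 0.13) and Tap2 (-1.80 ± 0.19) ranked first by p. The 30 tested interferon-gamma response genes held 18 that rose and 2 that fell (18 and 3 adjusted over the list alone, median 1.29, camera adjusted p = 3.6e-04 but 0.296). Cxcl9 (count ratio 789.6, 95% counting interval 141 to 31228), Ifi47 (1.96 ± 0.18) and Cxcl10 (4.57 ± 0.33) came first by p. Of 30 tested type I interferon response genes, 25 rose and 0 fell (25 and 0 adjusted over the list alone, median 2.84, camera adjusted p = 1.7e-15 but 0.111). Bst2 (1.97 ± 0.11), Ifi27l2a (3.96 ± 0.20) and Ifitm3 (4.15 ± 0.20) had the smallest p. Cxcl9 (log2 8.99 to 10.52 without control 1) moved over 1.5 times in fold on leaving out that library.

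Chemokine genes rose, while other inflammatory lists were mixed. Among 19 chemokine genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 3.43, camera adjusted p = 6.9e-13). Ccl5 (4.91 ± 0.16), Cxcl13 (7.58 ± 0.35) and Cxcl9 (count ratio 789.6, 95% counting interval 141 to 31228) ranked first by p. The 16 tested proinflammatory cytokine genes held 8 that rose and 2 that fell (9 and 2 adjusted over the list alone, median 0.71, camera adjusted p = 0.132). Il1a (1.16 ± 0.08), Il1b (1.45 ± 0.14) and Osm (-2.09 ± 0.41) came first by p. Of 26 tested NF-kappaB target genes, 6 rose and 8 fell (7 and 9 adjusted over the list alone, median -0.03, camera adjusted p = 0.719), while the mean was 0.41 and the test pointed up. Bcl2a1a (2.36 ± 0.17), Cflar (-1.06 ± 0.10) and Il1b (1.45 ± 0.14) had the smallest p. Among 20 inflammasome and cell death genes, 11 rose and 5 fell (11 and 5 adjusted over the list alone, median 0.43, camera adjusted p = 0.100). Bax (2.16 ± 0.10), Gsdmd (-1.83 ± 0.12) and Il1b (1.45 ± 0.14) ranked first by p. The 20 tested complement genes held 15 that rose and 1 that fell (15 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 0.00515 but 0.258). C3ar1 (0.74 ± 0.07) and Cfb (3.12 ± 0.27) were among the 3 with the smallest p. Of 17 tested costimulation and checkpoint genes, 4 rose and 6 fell (4 and 6 adjusted over the list alone, median -0.24, camera adjusted p = 0.622), while the mean was 0.28 and the test pointed down. 4632428N05Rik (-1.33 ± 0.07), Lgals9 (1.01 ± 0.06) and Cd40 (count ratio 389.8, 95% counting interval 69.6 to 15436) had the smallest p. Among 29 TAK1 and MAPK pathway genes, 5 rose and 15 fell (5 and 15 adjusted over the list alone, median -0.35, camera adjusted p = 0.0599), and the list was called lower under library totals (0.0270), with the replicate block (0.0432) or without control 4 (0.0456). Tnfrsf1b (-1.59 ± 0.11), Rela (-1.12 ± 0.11) and Traf2 (-1.03 ± 0.14) ranked first by p. The 16 tested TGF-beta signalling genes held 5 that rose and 1 that fell (5 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.634), and under library totals the median was -0.05. Skil (0.75 ± 0.07), Itgav (0.96 ± 0.11) and Nrros (-1.10 ± 0.13) came first by p. Cxcl9 (log2 8.99 to 10.52 without control 1) and Cd40 (log2 7.94 to 9.48 without control 2 or 7.03 without syngeneic 2) moved over 1.5 times in fold on leaving out that library.

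In the same libraries 6 of 8 nuclear non-coding RNAs and 20 of 21 mRNAs with detained introns fell, and 12 of 14 choroid plexus transcripts rose (summed 1806 ± 517 against 89.8 ± 55.4 CPM); these lists were made after the values were seen. Of 24 tested homeostatic microglia genes, 7 rose and 13 fell (7 and 13 adjusted over the list alone, median -0.32, camera adjusted p = 5.0e-04 but 0.178). Csf1r (-1.70 ± 0.08), Adgrg1 (-1.60 ± 0.08) and Tmem119 (-1.57 ± 0.08) had the smallest p. Among 24 disease-associated microglia genes, 15 rose and 3 fell (16 and 5 adjusted over the list alone, median 0.89, camera adjusted p = 3.0e-06 but 0.0681). Spp1 (3.38 ± 0.15), Lyz2 (1.66 ± 0.08) and Lpl (2.148 ± 0.13) ranked first by p. The 21 tested phagocytosis receptor genes held 12 that rose and 7 that fell (12 and 8 adjusted over the list alone, median 0.38, camera adjusted p = 0.169). Trem2 (-1.28 ± 0.07), Fcer1g (1.003 ± 0.06) and Tyrobp (0.91 ± 0.07) came first by p. Of 29 tested lysosomal genes, 13 rose and 9 fell (13 and 10 adjusted over the list alone, median 0.11, camera adjusted p = 0.607), while the mean was -1.2e-03 and the test pointed up, and under library totals the median was -0.06. Ctss (0.87 ± 0.05), Cd63 (1.13 ± 0.08) and Lamp2 (0.83 ± 0.07) had the smallest p. Among 17 border-associated macrophage markers, 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 2.12, camera adjusted p = 0.0219 but 0.111). Siglec1 (2.95 ± 0.31), Maf (0.80 ± 0.09) and Gas6 (1.12 ± 0.13) ranked first by p. The 25 tested markers of engrafted bone marrow-derived macrophages held 16 that rose and 1 that fell (16 and 1 adjusted over the list alone, median 1.46, camera adjusted p = 6.4e-07). Ly6e (2.73 ± 0.09), Cybb (3.62 ± 0.15) and Lyz2 (1.66 ± 0.08) came first by p. Of 19 tested monocyte markers, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.28, camera adjusted p = 0.0599), and the list was called higher under library totals (0.0228) or with the replicate block (0.0447). Ms4a4c (1.98 ± 0.20), Plac8 (3.10 ± 0.32) and Fn1 (2.96 ± 0.56) had the smallest p. Fn1 (3.87 without control 2) moved over 1.5 times in fold on leaving out that library.

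Cell cycle, p53 target and ribosomal genes rose (GC and length effects open). Among 45 cytosolic ribosomal protein genes, 44 rose and 0 fell (44 and 1 adjusted over the list alone, median 0.996, camera adjusted p = 5.3e-38 but 0.0603 with an estimated correlation). Rps19 (1.54 ± 0.07), Rps6 (1.52 ± 0.08) and Rps20 (1.27 ± 0.07) ranked first by p. The 35 tested oxidative phosphorylation genes held 29 that rose and 2 that fell (30 and 2 adjusted over the list alone, median 0.77, camera adjusted p = 2.8e-12 but adjusted p = 0.0603 with an estimated correlation). Cox6a1 (1.49 ± 0.07), Cox4i1 (1.21 ± 0.07) and Ndufa1 (1.59 ± 0.09) came first by p. Of 21 tested glycolysis genes, 8 rose and 8 fell (8 and 8 adjusted over the list alone, median 0.19, camera adjusted p = 0.710). Gapdh (1.41 ± 0.10), Pgk1 (1.16 ± 0.14) and Ldha (1.06 ± 0.13) had the smallest p. Among 22 cholesterol synthesis genes, 11 rose and 5 fell (11 and 5 adjusted over the list alone, median 0.44, camera adjusted p = 0.276). Idi1 (2.18 ± 0.30), Msmo1 (0.90 ± 0.14) and Insig1 (1.11 ± 0.18) ranked first by p. The 30 tested cell cycle genes held 30 that rose and 0 that fell (30 and 0 adjusted over the list alone, median 3.17, camera adjusted p = 2.7e-21). Top2a (4.36 ± 0.17), Rrm2 (3.97 ± 0.21) and Cdk1 (3.63 ± 0.20) came first by p. Of 27 tested p53 target genes, 16 rose and 3 fell (17 and 3 adjusted over the list alone, median 1.40, camera adjusted p = 8.6e-05). Cdkn1a (3.11 ± 0.09), Bax (2.16 ± 0.10) and Btg2 (-1.87 ± 0.11) had the smallest p. Among 14 senescence genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 1.10, camera adjusted p = 0.00136 but adjusted p = 0.0681 with an estimated correlation). Cdkn1a (3.11 ± 0.09), Hmgb2 (1.91 ± 0.10) and Hmgb1 (1.28 ± 0.08) ranked first by p. The 24 tested immediate early and dissociation genes held 4 that rose and 4 that fell (4 and 4 adjusted over the list alone, median -2.3e-04, camera adjusted p = 0.501). Btg2 (-1.87 ± 0.11), Zfp36 (-2.29 ± 0.14) and Hsp90aa1 (1.17 ± 0.09) came first by p.

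Several markers of other brain cells were higher and several lymphocyte markers lower than in control. Of 9 tested T cell markers, 1 rose and 5 fell (1 and 5 adjusted over the list alone, median -0.90, camera adjusted p = 0.319). Pdcd1 (-0.90 ± 0.20), Lat (at least 33.7-fold lower) and Skap1 (count ratio 0.0181, 95% counting interval 0.00370 to 0.0539) had the smallest p. Among 5 NK and cytotoxic cell markers, 1 rose and 2 fell (1 and 2 adjusted over the list alone, median 1.62 or 3.0e-03 with genes of 3 or fewer counts at their bound, camera adjusted p = 0.0876), and the list was called higher without control 3 (0.0386). Ccl5 (4.91 ± 0.16), Ctsw (count ratio 0.0105, 95% counting interval 0.00126 to 0.0384) and Klrd1 (-1.20 ± 0.37) ranked first by p. The 6 tested B and plasma cell markers held 1 that rose and 3 that fell (1 and 3 adjusted over the list alone, median -0.42, camera adjusted p = 0.501), while the mean was 0.35 and the test pointed down. Blnk (-0.70 ± 0.08), Bank1 (0.47 ± 0.15) and Cd22 (-0.88 ± 0.30) came first by p. Of 11 tested dendritic cell markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median -0.20, camera adjusted p = 0.923), while the mean was -0.36 and the test pointed up. Flt3 (-3.75 ± 0.40), Cst3 (0.41 ± 0.05) and Siglech (0.31 ± 0.05) had the smallest p. Among 8 neutrophil markers, 1 rose and 2 fell (1 and 1 adjusted over the list alone, median -1.75, camera adjusted p = 0.359). Csf3r (-0.80 ± 0.08), Trem3 (at least 32.1-fold higher) and Lcn2 (-4.76 ± 1.94) ranked first by p. The 19 tested astrocyte markers held 11 that rose and 1 that fell (11 and 1 adjusted over the list alone, median 2.91, camera adjusted p = 0.0219 but adjusted p = 0.215 with an estimated correlation). Slc1a2 (6.94 ± 0.71), Clu (3.05 ± 0.33) and S100b (6.12 ± 0.73) came first by p. Of 9 tested oligodendrocyte lineage markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone, median 1.002, camera adjusted p = 0.438). Mag (-1.15 ± 0.18), Enpp2 (3.67 ± 0.49) and Ermn (at least 37.8-fold higher) had the smallest p. Among 16 neuronal markers, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 3.09, camera adjusted p = 0.276). Atp1b1 (4.58 ± 0.73), Map2 (at least 114-fold higher) and Snap25 (2.60 ± 0.58) ranked first by p. The 16 tested endothelial and mural markers held 5 that rose and 5 that fell (5 and 5 adjusted over the list alone, median 0.23, camera adjusted p = 0.923), while the mean was 0.57 and the test pointed down. Ly6a (3.86 ± 0.43), Pdgfrb (-2.45 ± 0.38) and Slc2a1 (-0.90 ± 0.19) came first by p. Of 6 tested erythroid markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 1.46, camera adjusted p = 0.438). Car2 (4.83 ± 0.58), Tfrc (1.94 ± 0.33) and Bpgm (-0.34 ± 0.32, not called) had the smallest p. Among 2 sex-linked genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone, median -4.02). Xist (-4.42 ± 0.34) and Tsix (-3.62 ± 1.61, not called) ranked first by p. Klrd1 (0.05001 without control 3), Bank1 (0.0580 without control 2), Cd22 (0.0798 without control 3) and Lcn2 (0.0644 to 0.131 without control 1, 3, 4 or syngeneic 1, 3, 4) lost the edgeR call at these adjusted p. Tsix (0.00440 without syngeneic 1) gained a call at that edgeR adjusted p. Skap1 (log2 -5.47 to -8.31 without syngeneic 3), Ctsw (log2 -6.34 to -8.54 without syngeneic 1), Trem3 (log2 7.51 to 6.87 without syngeneic 1), Lcn2 (-4.10 without control 4 or -7.76 without syngeneic 2), Slc1a2 (7.81 without control 1), S100b (7.07 without control 1), Ly6a (4.61 without control 2), Car2 (5.94 without control 2) and Tsix (-8.64 without syngeneic 1) moved over 1.5 times in fold on leaving out that library. Siglech turned to -7.9e-04 with the GC and length offset.

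Allogeneic recipients were also compared with untransplanted controls, again without knowledge of batch. Ccl5, a chemokine for T cells, stood at 1153 ± 114 against 1.85 ± 0.590 CPM (log2 fold change 9.27, SE 0.19, edgeR adjusted p = 1.9e-16), and Cd74 at 13689 ± 1467 against 60.4 ± 6.76 CPM. Csf1r fell from 11490.5 ± 1079 to 2879 ± 170.2 CPM, and the microglial marker Tmem119 from 3971 ± 491 to 1139 ± 48.1 CPM (log2 fold change -1.80, SE 0.08, edgeR adjusted p = 5.9e-13). Of 12695 genes tested, 7273 were called, 3576 higher and 3697 lower. With library totals only, 7712 were called, 2453 higher and 5259 lower, and the median log2 fold change of all genes was -0.44. Among all tested genes, 6836 (53.8%) had no overlap between the groups, where exchangeable libraries give 2.86%. The largest rises without overlap were those of Cxcl9 (count ratio 61786, 95% counting interval 11089 to 2440490.0), Iigp1 (count ratio 38388, 95% counting interval 6889 to 1516310.0), Cxcl13 (11.71 ± 0.36), Cxcl11 (9.78 ± 0.58), Ccl5 (9.27 ± 0.19) and Ccl7 (8.95 ± 0.76), where Ccl7 attracts monocytes. The largest falls were those of Malat1 (-6.14 ± 0.50), Hdac10 (-5.31 ± 0.36), Snhg20 (-5.08 ± 0.24), Sfi1 (-4.77 ± 0.14), Rgl2 (-4.40 ± 0.16) and Tmem181b-ps (-4.36 ± 0.33). Cxcl9 (log2 15.30 to 16.82 without control 1), Iigp1 (log2 14.61 to 16.13 without control 2), Cxcl11 (11.51 without control 2) and Ccl7 (9.97 without control 3) moved over 1.5 times in fold on leaving out that library.

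All 4 lists of antigen presentation and interferon response were called higher. The 13 tested MHC class II presentation genes held 12 that rose and 1 that fell (12 and 1 adjusted over the list alone, median 2.66, camera adjusted p = 3.4e-20). Cd74 (7.82 ± 0.15), H2-Ab1 (5.13 ± 0.12) and Ctss (1.78 ± 0.05) came first by p. Of 20 tested MHC class I presentation genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, median 1.83, camera adjusted p = 9.0e-20). B2m (3.32 ± 0.07), H2-Q4 (4.37 ± 0.15) and H2-K1 (4.69 ± 0.14) had the smallest p. Among 30 interferon-gamma response genes, 28 rose and 0 fell (29 and 1 adjusted over the list alone, median 4.58, camera adjusted p = 1.1e-18). Ifi47 (5.72 ± 0.20), Gbp7 (3.32 ± 0.12) and Gbp3 (3.63 ± 0.15) ranked first by p. The 30 tested type I interferon response genes held 30 that rose and 0 that fell (30 and 0 adjusted over the list alone, median 4.88, camera adjusted p = 1.5e-26). Bst2 (4.01 ± 0.12), Ifi27l2a (6.09 ± 0.22) and Ifitm3 (7.01 ± 0.23) came first by p.

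Inflammatory mediators were mostly higher than in control. Of 19 tested chemokine genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 6.21, camera adjusted p = 3.0e-19). Ccl5 (9.27 ± 0.19), Cxcl13 (11.71 ± 0.36) and Cxcl9 (count ratio 61786, 95% counting interval 11089 to 2440490.0) had the smallest p. Among 16 proinflammatory cytokine genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 1.98, camera adjusted p = 1.3e-04). Il1b (4.25 ± 0.15), Il1a (2.03 ± 0.08) and Tnfsf13b (1.78 ± 0.19) ranked first by p. The 26 tested NF-kappaB target genes held 13 that rose and 3 that fell (14 and 3 adjusted over the list alone, median 0.78, camera adjusted p = 0.00240 but adjusted p = 0.217 with an estimated correlation). Il1b (4.25 ± 0.15), Bcl2a1a (4.72 ± 0.19) and Sod2 (2.03 ± 0.12) came first by p. Of 20 tested inflammasome and cell death genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone, median 1.20, camera adjusted p = 4.7e-04). Il1b (4.25 ± 0.15), Bax (2.56 ± 0.10) and Pycard (1.21 ± 0.07) had the smallest p. Among 20 complement genes, 19 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.95, camera adjusted p = 2.4e-06 but 0.0642). Cfb (7.08 ± 0.30), C1qa (1.14 ± 0.06) and C1qb (1.10 ± 0.07) ranked first by p. The 17 tested costimulation and checkpoint genes held 10 that rose and 2 that fell (10 and 2 adjusted over the list alone, median 0.97, camera adjusted p = 0.0363 but adjusted p = 0.398 with an estimated correlation), and the call was lost under library totals (0.0826), without control 2 (0.0528) or without control 4 (0.0577). 4632428N05Rik (-1.79 ± 0.07), Lgals9 (1.32 ± 0.06) and Cd48 (1.12 ± 0.08) came first by p. Of 29 tested TAK1 and MAPK pathway genes, 4 rose and 14 fell (6 and 15 adjusted over the list alone, median -0.33, camera adjusted p = 0.0765), and the list was called lower under library totals (0.0248). Tnfrsf1b (-1.78 ± 0.11), Rela (-1.48 ± 0.11) and Tlr2 (1.70 ± 0.15) had the smallest p. Among 16 TGF-beta signalling genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone, median -0.13, camera adjusted p = 0.820), while the mean was 0.13 and the test pointed down. Skil (0.71 ± 0.07), Tgfbr2 (0.65 ± 0.07) and Itgav (0.77 ± 0.11) ranked first by p. Cxcl9 (log2 15.30 to 16.82 without control 1) moved over 1.5 times in fold on leaving out that library.

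In the same libraries 7 of 8 nuclear non-coding RNAs and 20 of 21 mRNAs with detained introns fell, and 11 of 14 choroid plexus transcripts rose (summed 608 ± 159.9 against 89.8 ± 55.4 CPM); these lists were made after the values were seen. The 24 tested homeostatic microglia genes held 3 that rose and 19 that fell (3 and 20 adjusted over the list alone, median -0.97, camera adjusted p = 4.1e-12). Adgrg1 (-2.17 ± 0.08), Csf1r (-2.00 ± 0.08) and Ecscr (-2.54 ± 0.10) came first by p. Of 24 tested disease-associated microglia genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone, median 1.51, camera adjusted p = 3.2e-16). Lyz2 (3.18 ± 0.09), Fth1 (2.34 ± 0.06) and Spp1 (5.598 ± 0.16) had the smallest p. Among 21 phagocytosis receptor genes, 16 rose and 5 fell (16 and 5 adjusted over the list alone, median 0.93, camera adjusted p = 0.00116). Clec7a (3.92 ± 0.15), Fcer1g (1.45 ± 0.06) and Tyrobp (1.47 ± 0.07) ranked first by p. The 29 tested lysosomal genes held 16 that rose and 7 that fell (16 and 7 adjusted over the list alone, median 0.38, camera adjusted p = 5.1e-04 but 0.219). Ctss (1.78 ± 0.05), Ctsl (1.69 ± 0.07) and Cd63 (1.94 ± 0.08) came first by p. Of 17 tested border-associated macrophage markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.98, camera adjusted p = 0.0765), and the list was called higher under library totals (0.0235), without control 1 (0.0482) or without control 3 (0.0295). Siglec1 (6.65 ± 0.34), Stab1 (-1.46 ± 0.09) and Cd36 (8.41 ± 0.73) had the smallest p. Among 25 markers of engrafted bone marrow-derived macrophages, 22 rose and 2 fell (22 and 2 adjusted over the list alone, median 3.29, camera adjusted p = 1.6e-14). Ly6e (3.79 ± 0.10), Lyz2 (3.18 ± 0.09) and Cybb (6.61 ± 0.17) ranked first by p. The 19 tested monocyte markers held 12 that rose and 1 that fell (12 and 1 adjusted over the list alone, median 1.85, camera adjusted p = 0.00478). Ms4a4c (4.90 ± 0.22), Plac8 (5.81 ± 0.35) and Fn1 (7.16 ± 0.61) came first by p. Cd36 (9.12 without control 4) and Fn1 (8.05 without control 2) moved over 1.5 times in fold on leaving out that library.

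Ribosomal, respiratory chain, cell cycle and p53 target genes rose (GC and length effects open). Of 45 tested cytosolic ribosomal protein genes, 44 rose and 0 fell (44 and 0 adjusted over the list alone, median 1.89, camera adjusted p = 2.0e-83). Rps20 (2.53 ± 0.07), Rpl32 (2.28 ± 0.06) and Rps19 (2.496 ± 0.07) had the smallest p. Among 35 oxidative phosphorylation genes, 31 rose and 2 fell (32 and 2 adjusted over the list alone, median 1.21, camera adjusted p = 1.3e-16). Cox6a1 (1.98 ± 0.07), Cox4i1 (1.86 ± 0.07) and Ndufa1 (2.31 ± 0.09) ranked first by p. The 21 tested glycolysis genes held 9 that rose and 6 that fell (9 and 6 adjusted over the list alone, median 0.38, camera adjusted p = 0.192). Gapdh (2.12 ± 0.11), Ldha (1.82 ± 0.13) and Pgk1 (1.60 ± 0.14) came first by p. Of 22 tested cholesterol synthesis genes, 15 rose and 3 fell (15 and 3 adjusted over the list alone, median 0.74, camera adjusted p = 0.0811), and the list was called higher without allogeneic 1 (0.0442). Insig1 (1.79 ± 0.19) and Msmo1 (1.21 ± 0.14) were among the 3 with the smallest p. Among 30 cell cycle genes, 28 rose and 0 fell (29 and 0 adjusted over the list alone, median 2.93, camera adjusted p = 1.4e-11). Top2a (4.01 ± 0.17), Rrm2 (3.96 ± 0.21) and Cdk1 (3.44 ± 0.20) ranked first by p. The 27 tested p53 target genes held 18 that rose and 3 that fell (19 and 4 adjusted over the list alone, median 1.56, camera adjusted p = 4.0e-04). Cdkn1a (3.16 ± 0.09), Bax (2.56 ± 0.10) and Btg2 (-2.18 ± 0.11) came first by p. Of 14 tested senescence genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 1.27, camera adjusted p = 0.00269). Cdkn1a (3.16 ± 0.09), Hmgb2 (1.76 ± 0.10) and Hmgb1 (1.26 ± 0.08) had the smallest p. Among 24 immediate early and dissociation genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone, median 0.18, camera adjusted p = 0.484), while the mean was -0.14 and the test pointed down, and under library totals the median was -0.19. Btg2 (-2.18 ± 0.11), Zfp36 (-2.04 ± 0.14) and Hsp90aa1 (1.03 ± 0.08) ranked first by p.

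Markers of other brain cells and of lymphocytes were again set against control. The 9 tested T cell markers held 1 that rose and 3 that fell (1 and 3 adjusted over the list alone, median -0.67, camera adjusted p = 0.439). Icos (-2.28 ± 0.55), Cd27 (count ratio 0.0116, 95% counting interval 0.00237 to 0.0341) and Skap1 (count ratio 0.0219, 95% counting interval 0.00448 to 0.0653) came first by p. Of 5 tested NK and cytotoxic cell markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone, median 6.19 or 6.14 with genes of 3 or fewer counts at their bound, camera adjusted p = 0.00627). Ccl5 (9.27 ± 0.19), Klrd1 (-2.17 ± 0.38) and Klrb1c (at least 70.5-fold higher) had the smallest p. Among 6 B and plasma cell markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone, median -0.51, camera adjusted p = 0.307), while the mean was 0.29 and the test pointed down. Blnk (-0.94 ± 0.08), Tnfrsf17 (-1.37 ± 0.23) and Cd22 (1.61 ± 0.30) ranked first by p. The 11 tested dendritic cell markers held 2 that rose and 4 that fell (2 and 4 adjusted over the list alone, median -0.28, camera adjusted p = 0.607). Naaa (1.95 ± 0.16), Fscn1 (-0.58 ± 0.09) and Flt3 (-2.38 ± 0.37) came first by p. Of 8 tested neutrophil markers, 1 rose and 2 fell (1 and 1 adjusted over the list alone, median -0.94, camera adjusted p = 0.607). Csf3r (-0.70 ± 0.08), Trem3 (at least 103-fold higher) and Ngp (-5.32 ± 2.05) had the smallest p. Among 19 astrocyte markers, 10 rose and 3 fell (11 and 3 adjusted over the list alone, median 2.45, camera adjusted p = 0.0964), and the list was called higher under library totals (0.0235) or without control 2 (0.0435). Slc1a2 (6.24 ± 0.69), Glul (-0.71 ± 0.08) and S100b (5.59 ± 0.72) ranked first by p. The 9 tested oligodendrocyte lineage markers held 6 that rose and 1 that fell (6 and 2 adjusted over the list alone, median 2.03, camera adjusted p = 0.607). Mag (-1.004 ± 0.18), Enpp2 (2.03 ± 0.46) and Mobp (3.42 ± 1.05) came first by p. Of 16 tested neuronal markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone, median 2.47, camera adjusted p = 0.409). Atp1b1 (3.98 ± 0.71), Map2 (at least 32.4-fold higher) and Snap25 (2.38 ± 0.58) had the smallest p. Among 16 endothelial and mural markers, 4 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.65, camera adjusted p = 0.731). Ly6a (8.77 ± 0.47), Pecam1 (-1.34 ± 0.28) and Pdgfrb (-1.25 ± 0.36) ranked first by p. The 6 tested erythroid markers held 2 that rose and 1 that fell (2 and 1 adjusted over the list alone, median 1.84, camera adjusted p = 0.584). Car2 (3.96 ± 0.56), Tfrc (1.85 ± 0.33) and Bpgm (-0.93 ± 0.32) came first by p. Of 2 tested sex-linked genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone, median -5.71 or -4.32 with genes of 3 or fewer counts at their bound). Xist (-2.76 ± 0.31) and Tsix (at least 58.9-fold lower) had the smallest p. With an estimated correlation between genes in place of the preset 0.01, camera calls held for 20 of 22 lists in allogeneic against syngeneic (adjusted p 7.2e-05 to 0.0497). They held for 4 of 15 in syngeneic against control (chemokines, cell cycle, engrafted macrophages and p53 targets, 0.0182 to 0.0423). In allogeneic against control they held for 19 of 23 (0.00439 to 0.0377). Ngp (0.0572 to 0.0902 without control 1, 3, 4 or allogeneic 1, 2, 4) and Bpgm (0.0630 to 0.116 without control 2 or allogeneic 3) lost the edgeR call at these adjusted p. Icos (-2.99 without allogeneic 3), Cd27 (log2 -6.19 to -9.17 without allogeneic 3), Skap1 (log2 -5.38 to -8.31 without allogeneic 2), Ngp (-4.70 without control 4 or -11.13 without allogeneic 3), Slc1a2 (7.11 without control 1), S100b (6.53 without control 1), Mobp (4.30 without control 1), Ly6a (9.50 without control 2) and Car2 (5.06 without control 2) moved over 1.5 times in fold on leaving out that library. Fscn1 turned to 0.35 and Csf3r to 0.03 with the GC and length offset.

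Both transplanted groups were set against the same 4 controls. In total 5619 genes were called in the same direction in both, 2892 higher and 2727 lower, which is 85.0% of the syngeneic calls. Independent lists of these sizes would share 946 higher and 947 lower genes, which leaves out the shared controls, and 20 simulated pairs of unchanged groups, which leave out the effects, shared 0, so neither figure tests a shared effect. The fold changes correlated across 9225 genes, which are not independent replicates, with r = 0.894, against 0.476 to 0.532 in the simulations; the covariance was 1.10 against a simulated 0.0264. With the controls split into separate pairs, 4503 to 4566 genes were shared and r was 0.846 to 0.865. Of the genes higher in both, 757 were higher still in allogeneic than in syngeneic libraries, 82 were nearer control, and for 2053 the difference was not called; of those lower in both the numbers were 293, 77 and 2357. Another 55 genes were called in opposite directions, 26 of them higher in syngeneic and lower in allogeneic libraries, among them Fcrls and P2ry12, and 29 the reverse, among them Irf1. With library totals as the only scaling, 49 of the 55 kept opposite directions and 25 both calls. The GC and length offset left 41 (not P2ry12) and 17.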

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

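Tests chosen only after the result was seen are the GC and length offset, the batch count and the lineage transcripts. The same holds for the counts of fixed-list genes below 1 CPM, the H2-Ea-ps ratio and the macrophage markers. The 3 counts of splits were planned beforehand. The long non-coding RNA class and the opposite calls were set after gene values were seen but before their own results. The nuclear, lineage and choroid gene lists were drawn up after values were seen. In each comparison only the real split of the 8 libraries, 1 of 35, gave as many called genes. The count was 2098 against a highest other of 1 for allogeneic against syngeneic. It was 6610 against 3 for syngeneic against control and 7273 against 0 for allogeneic against control. Mixed splits put the group difference into the spread, which made few calls likely in advance. These counts therefore exclude neither chance nor a batch that follows the groups.

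For 68 of 684 gene values and library measures tested, 1 library of 4 stood apart, its gap to the nearest exceeding 0.829 of the group's range, where chance alone gives about 1 in 20 (34.2). The share of the range is given after each gene; several have a handful of counts. Control 1 was highest for Cd38 (0.866), Cxcl9 (1), Lgals9 (0.898), Msmo1 (0.910) and S100b (0.853). Control 2 was highest for Bcas1 (1), Cd40 (1), Cxcl11 (0.877), Iigp1 (1), Kl (0.842), Klrk1 (1) and Ly6a (0.885) and lowest for Cox6a1 (0.861), Gapdh (0.851) and Rela (0.841). Control 3 was highest for Sfi1 (0.948) and lowest for Klf6 (0.886). Control 4 was highest for H2-Ea-ps (0.908), Hdc (0.943) and Slc4a1 (1). Syngeneic 1 was highest for Atp1b1 (0.903), Clk1 (0.867), Ctsw (1), Enpp2 (0.958), Fn1 (0.904), Folr1 (0.831), Icos (0.980), Klrb1c (1), Neat1 (0.837), Slc4a1 (0.986) and Tsix (1) and lowest for B2m (0.886). Syngeneic 2 was highest for Cd27 (1), Cd40 (0.853), Gapdh (0.886), Hdc (1), Lcn2 (1) and Snap25 (0.894). Syngeneic 3 was highest for Flt1 (1), Ifi47 (0.955) and Skap1 (1) and lowest for Nrgn (0.884). Syngeneic 4 was highest for Cd38 (0.923), Ciita (1), Ngp (1) and Pdcd1 (0.862) and lowest for Lamp2 (0.841), Top2a (0.829) and Tyrobp (0.848). Allogeneic 1 was highest for Ctsw (1) and lowest for Itgav (0.901). Allogeneic 2 was highest for Ctsl (0.945), Lcn2 (0.862) and Skap1 (1). Allogeneic 3 was highest for Cd27 (1), Cd3e (0.915), Cxcl9 (0.834), Irf1 (0.959), Klhdc8b (0.875), Ms4a4c (0.914), Neat1 (0.933), Ngp (1), Pecam1 (0.886), Skil (0.882) and Tlr4 (0.913) and lowest for Cd63 (0.879). Allogeneic 4 was highest for Cspg4 (0.912) and lowest for Hmgb1 (0.908).

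Called in opposite directions against control in the 2 transplanted groups, with a called difference between them, were 55 genes. Among named genes the log2 fold changes of allogeneic minus syngeneic were Bank1 -1.23, Cd22 2.49, Cd300lf 2.62, Cst3 -0.70, Fcrls -2.32, Fscn1 -1.09, Gpr34 -0.94, Icam1 1.08, Irf1 2.29, P2ry12 -0.93, Ski -0.45 and Slamf8 1.69. With library totals only, 49 of the 55 kept opposite directions and 45.5% (25 genes) also both calls, but that setting moves the 55 by nearly 1 constant per group (log2 -0.19 to -0.16 in syngeneic and -0.39 to -0.37 in allogeneic against control), where the size and SE of each fold decide which stay, so both a shift from the composition factors and GvHD, untested, stay open. With the GC and length offset 41 kept opposite directions and 17 both calls (11 did under both settings): Gpr34 and P2ry12 turned in syngeneic and Fscn1 and Ski in allogeneic against control, and Bank1, Cd22, Cd300lf and Icam1 lost the syngeneic call, while leaving out 1 library also ended a call against control for Bank1 (edgeR adjusted p = 0.0580), Cd22 (0.0798), Cd300lf (0.0622 to 0.136), Icam1 (0.0683) and Ski (0.0624 to 0.101). This test was dropped for a time after its result was seen, then restored, and it was judged void only after its values were seen.

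The second pattern is lower nuclear RNA in both transplanted groups than in control: 26 of 29 nuclear and detained-intron genes fell in syngeneic and 27 in allogeneic libraries, the former with a median log2 fold change of -2.14 (bootstrap interval -2.49 to -1.55). After an offset for GC content and length it was -2.32 (-2.78 to -1.65), which argues against those trends as the cause. The 428 other long non-coding RNA genes lay -0.89 from matched coding genes in syngeneic and -1.03 in allogeneic libraries, so a smaller nuclear share of the RNA may contribute, for instance from a difference in sorting or extraction. Irradiation and transplantation as such cannot be told apart from a batch, since the labels tie 0 libraries of control and transplanted mice to 1 batch.

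The third pattern is the rise of MHC class II and interferon-gamma response genes in allogeneic libraries, for which GvHD acting on microglia, the design's own explanation, stays open. Transcripts of T, NK, B and dendritic cells and neutrophils argue against those cells as the main source. Of 17 chosen after values were seen, the highest, S100a8, averaged 2.23 CPM, beside 13689 for Cd74. The fixed NK and cytotoxic list was called higher (3 of 5 tested genes rose, camera adjusted p = 2.3e-06), with Ccl5 at 1153 CPM and Klrk1 at 27.1. The Klrk1 call ended without syngeneic 1, 2, 4 or any 1 allogeneic library. Below 1 CPM in allogeneic libraries were 15 of 19 genes of this list, 25 of 29 T cell and 18 of 21 neutrophil genes. So were 13 of 18 B and plasma and 12 of 20 dendritic cell genes, which argue less firmly. The H2-Ea-ps to H2-Aa count ratio was 1.18 times (SE 0.0528) its syngeneic value, which argues against donor cells that lack H2-Ea transcripts, though the labels name no donor strain. Engrafted bone marrow-derived macrophages stay open, since 1 of 3 markers outside the interferon lists rose (Ms4a7, whose call ended without syngeneic 3, 4 or allogeneic 2, 4, at edgeR adjusted p of 0.0516 to 0.0621), while Cd38, not called at 4.24, gained a call at 7.31 (edgeR adjusted p = 0.0124) without syngeneic 4.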

How the results depend on the processing

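Counts of called genes stayed within 1.5 times under every alternative except the fold change limit of 1 log2 unit, which by construction keeps fewer: 625 in allogeneic against syngeneic, 3223 in syngeneic against control and 4204 in allogeneic against control. Called lists in syngeneic against control fell to 4 with an estimated correlation and were 32 by fry, and in allogeneic against control 36 by fry, which tests each list alone. Leaving out 1 library gave 1768 (without allogeneic 3) to 1989, 6189 to 6302 and 6860 to 7109 genes, and 21 to 23, 15 to 17 and 22 to 24 lists. With the replicate number as a block the counts were 2002, 6507 and 7200 genes, 23, 17 and 23 lists, and 5537 genes shared; same-number libraries correlated at -0.01 to 0.03, and 2, 1 and 1 of 4 matched best by number, so the numbers do not pair them. Genes shared by both transplanted groups ranged from 4503 with split controls to 6000 with limma-voom. Under library totals only, the median of all genes moved to -0.22, -0.20 and -0.44, and direction turned in allogeneic against control for Icam1 -0.039, Itgam -0.17, Klf6 -0.12, Maf -0.13 and Siglech -0.12. With the GC and length offset, added after seeing the data, it turned in syngeneic against control for Cd48 -0.056, Cd86 -0.11, Gpr34 -0.14, Klhdc8b 0.71, Mapk14 0.048, P2ry12 -0.037, Ptprc -0.20, Rhob 0.085 and Siglech -7.9e-04, and in allogeneic against control for Csf3r 0.027, Fscn1 0.35, Klf6 -0.013, Pmepa1 0.30, Siglech -0.13, Ski 0.63, Slc2a1 0.12, Smad3 0.24 and Tap2 0.24; the cause was not tested. Over named genes and all alternatives, 10690 values kept their side of the threshold, 269 lost the call and 117 gained one. Another 23 turned direction with a call before or after the change. Turns where neither value was called, such as that of Cspg4 without allogeneic 4, count among the 10690. The turned genes listed above leave such values out too. Depth limits genes with a group total of 0 to 3 counts, where ratios have wide intervals.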

Other observations

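Levels below are means ± SD (n = 4) in control, syngeneic and allogeneic libraries. Choroid plexus transcripts had their highest mean in syngeneic libraries, namely Ttr (53.7 ± 35.8, 1312 ± 375 and 446 ± 106 CPM), which encodes a thyroid hormone carrier, Folr1 (0.732 ± 0.228, 7.35 ± 4.50 and 2.68 ± 0.845 CPM), Kcnj13 (0.903 ± 0.992, 19.5 ± 10.99 and 6.11 ± 2.62 CPM) and Kl (0.335 ± 0.525, 12.3 ± 5.53 and 3.59 ± 1.71 CPM). Splicing kinase genes Clk1 (461 ± 18.7, 41.2 ± 4.66 and 41.7 ± 7.29 CPM) and Clk4 (106 ± 13.6, 23.5 ± 2.46 and 25.3 ± 3.06 CPM) and the nuclear RNA Neat1 (39.2 ± 5.14, 1.55 ± 1.52 and 0.947 ± 1.56 CPM) were lower in both transplanted groups. The T cell gene Cd3e (0 ± 0, 0 ± 0 and 0.0853 ± 0.153 CPM) stayed near the floor, and Ifng had 0 counts in the 12 libraries, so its level lies below the floor of each group. The class II transactivator Ciita (0.675 ± 0.828, 0.101 ± 0.202 and 9.08 ± 3.05 CPM) had its highest mean in allogeneic libraries, as had Cd38 (0.0627 ± 0.0912, 0.0953 ± 0.173 and 1.84 ± 0.576 CPM) and Clec12a (0.192 ± 0.212, 1.02 ± 0.277 and 4.94 ± 2.33 CPM). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every library.

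A hypothesis set up after the values were seen is that choroid plexus cells or their free RNA entered the sorted fraction, which FACS gates would be meant to remove. Its 13 genes with at least 1 CPM moved together between allogeneic and syngeneic libraries, with an SD of log2 fold changes of 0.345 around a median of -1.47, so such a source may explain them. Enpp2 is also in the oligodendrocyte list.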
